A study of Hydra vulgaris with 36 samples.

How the data were processed

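Whole animals of Hydra vulgaris, a freshwater cnidarian polyp, of the Basel strain were starved for 24 h and kept for 48 h in 20 µM DAPT with 1% DMSO, or in 1% DMSO alone as the control, per the labels' protocols. DAPT is an inhibitor of gamma-secretase, the protease complex whose cleavage of the Notch receptor releases its intracellular part. Both solutions were replaced with fresh ones at intervals of 12 h. Collection took place at the end of the incubation (0 h), and 3 h and 6 h after DAPT had been replaced by 1% DMSO, with about 25 animals per sample. Each of the 6 groups had 6 biological replicates, per the labels, which gave 36 libraries. The libraries were made with a strand-specific mRNA kit and sequenced on 3 lanes of an Illumina HiSeq2000 with a 100 bp read length. Which sample ran on which lane is not given in the sources used here, so no lane effect was tested.

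Per the labels, adapters, polyA stretches and splice leader sequences were removed from the reads, and reads with a quality score under 20, a length under 30 bp or an undetermined base were discarded. The submitters' processing notes name RSEM, Bowtie2 and DESeq2 1.18.1 without saying what each was used for. The authors deposited expected counts (estimated read counts that need not be whole) per gene in 1 table of 12410 genes and 36 columns, and 98.95% of its values were not whole. The gene identifiers are those of a Trinity de novo assembly, and how the assembly was made, its sequences and its annotation are not given in the sources used here. The deposited table holds no value of 0, with a lowest value of 0.09. A gene that was at 0 in any library is therefore outside the analysis, and a gene switched off to 0 or on from 0 would not be seen. Whether the assembly holds transcripts of other organisms was not checked.

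Columns were matched to samples by number, time and letter. The columns carry the letter S or P in place of the treatment, and the labels do not spell out either letter. S was read as DMSO and P as DAPT, because S occurs in the word DMSO and not in DAPT, and P in DAPT and not in DMSO. Under the opposite reading every direction of DAPT against DMSO would be mirrored, while the numbers of genes called between DAPT and DMSO and the sizes of these differences would stay. Comparisons over time within DMSO and within DAPT would trade places.

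The expected counts were rounded to whole numbers for the count tests, after which 186 values were 0. Genes were filtered with filterByExpr of edgeR 4.0.16 under R 4.3.3, which left 12253 genes and removed 157. Library sizes were scaled with TMM factors, which ranged from 0.6263 in DMSO 6 h replicate 4 to 1.372. edgeR's quasi-likelihood F test was fitted once over all 36 libraries with 6 group means, so that the groups shared an estimate of the spread per gene. A gene was called when its Benjamini-Hochberg (BH) adjusted p over all tested genes was under 0.05. Standard errors (SE) are those implied by the F statistic of each log2 fold change. CPM values are counts-per-million after TMM scaling, given as mean ± SD. The contrasts were DAPT against DMSO at each time, the change of that difference from 0 h to 3 h and to 6 h, and DMSO at 3 h and at 6 h against DMSO at 0 h. Each time had its own control libraries, so the 3 DAPT comparisons share none.

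Single values were compared between groups of 6 libraries with two-sided exact permutation tests, whose smallest possible p for 6 against 6 is 0.00216. To follow the genes of 0 h at later times free of their selection, genes were called at 0 h separately in the odd-numbered and in the even-numbered replicates. For each library, the log2 CPM difference from the mean DMSO library of its time was regressed through the origin on the 0 h log2 fold changes of the called genes, with a prior count of 2. A 0 h library was scored only on genes and fold changes of the replicates it did not belong to, and libraries of 3 h and 6 h on the average of both. Because the fold changes of called genes are inflated by their selection, the mean DAPT library of 0 h itself lies below 1 on this scale, and the DMSO libraries lie around 0 by construction. Responses at 3 h and 6 h are therefore given relative to 0 h, each as the mean DAPT slope minus the mean DMSO slope. Permutations of the time labels treat the slopes of different times as interchangeable. Slopes at 0 h and at later times were built differently, so the p of these permutations, though enumerated in full, are approximate.

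The comparisons, the tests, the filters, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were other size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), other low-count filters, the replicate number as a block, each replicate number left out in turn, separate fits per time, and stricter thresholds. Added after seeing the data were a fit without DMSO 6 h replicate 4, surrogate variables from sva 3.50.0, and time within the DAPT animals. Calling the genes in one set of replicates and measuring them in the other was fixed beforehand, while its form as a slope per library with a permutation test was added. The 18 gene lists fixed beforehand (Notch pathway, nematocyte, neuron and gland markers among them) were not tested, because 0 of the Trinity identifiers are paired with a name in the reference table used here. For unnamed identifiers the rule took the 2 with the smallest p that fell and the 2 that rose at 0 h. TRINITY_DN624_c0_g1 was added after its values were seen. A Trinity gene can be a fragment or a near-identical copy of another, and such genes can share reads.

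Libraries held between 5692414 and 15310480 counts. In counts simulated from the means and sizes of these libraries, with 50 genes changed at each of 4 fold sizes among 12253, the test of DAPT against DMSO at 0 h recovered 18% of the genes changed by 1.5-fold, 54% at 2-fold, 98% at 4-fold and 96% at 8-fold, and called 7 unchanged genes. For the change of the difference from 0 h to 6 h it recovered 4%, 20%, 84% and 88% at the same fold sizes and called 4 unchanged genes, and for DMSO at 6 h against 0 h 20%, 44%, 90% and 98%, with 6 unchanged genes called. The simulated genes varied independently of each other. The number of changed genes moves the BH threshold, so recovery in the real comparisons can differ from these values. No pair of libraries of a group was a duplicate: over the 90 pairs, the chi-square statistic per degree of freedom ranged from 10.0 to 205 over genes with at least 10 counts, where sampling noise alone gives about 1.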

Results

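Gene expression was measured by strand-specific mRNA sequencing of whole Hydra after 48 h with the gamma-secretase inhibitor DAPT or with its solvent DMSO, at 0 h, 3 h and 6 h after the inhibitor was removed. The stated purpose was to find transcriptional targets of Notch signalling from the differences between treated and control animals at the 3 times. Each of the 6 groups held 6 libraries. The total counts per library were 8564579 to 14060485 in DMSO and 8518484 to 15310480 in DAPT at 0 h, 6563592 to 12684174 and 6617621 to 9971841 at 3 h, and 5692414 to 10127546 and 7529491 to 10913483 at 6 h. Values below are means ± SD with n = 6 libraries per group. The 20 most abundant genes took between 23% and 40.9% of the counts of a library. Genes carry Trinity identifiers without names, so they are described by direction, abundance and time course. All directions rest on reading the column letters S and P as DMSO and DAPT, and would be mirrored if the letters meant the opposite, in which case the values over time given for control animals would be those of DAPT animals.

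At 0 h, with DAPT still present, the transcripts that differed were mostly lower in the treated animals. Of 12253 genes tested, 691 were lower in DAPT and 232 were higher, so that 74.9% of the 923 called genes were lower. The lower genes had a median log2 fold change of -1.42, with quartiles at -0.95 and -2.05, and 498 of them differed at least 2-fold and 187 at least 4-fold. The higher genes had a median log2 fold change of 1.07, with quartiles at 0.73 and 1.52, and 124 differed at least 2-fold and 27 at least 4-fold. The extremes were -5.34 and 4.97 on the log2 scale. In 391 of the 691 lower genes and 159 of the 232 higher genes all 6 DAPT libraries lay beyond all 6 DMSO libraries. Chance gives this for 0.216% of genes not selected on their values, in either direction, which is no reference rate for genes called on the same libraries.

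Both sets came from across the range of abundance. In DMSO at 0 h the median gene of the lower set stood at 8.07 CPM and of the higher set at 7.56 CPM, against 7.04 CPM for all tested genes, and 61 of the lower and 23 of the higher genes reached at least 100 CPM. In DAPT at 0 h the medians were 2.71 CPM for the lower and 17.7 CPM for the higher genes. Together the lower genes took 15.2 ± 5.80% of all counts in DMSO and 5.44 ± 1.23% in DAPT. The higher genes took 1.71 ± 0.141% in DMSO and 4.72 ± 0.401% in DAPT. These 0 h shares were not tested, since the genes were chosen on the same libraries.

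The pair of falling genes with the smallest p had nearly equal fold changes. TRINITY_DN629_c0_g1 stood at 84.6 ± 19.4 CPM in DMSO and 4.53 ± 1.02 CPM in DAPT, an 18.7-fold difference (log2 fold change -4.22, SE 0.20, edgeR adjusted p = 3.52e-17). TRINITY_DN448_c0_g1 stood at 70.5 ± 19.5 and 3.74 ± 0.857 CPM, an 18.9-fold difference (log2 fold change -4.24, SE 0.21, edgeR adjusted p = 3.52e-17). Of the rising pair, TRINITY_DN2171_c0_g1 was low in control animals, at 0.518 ± 0.201 CPM, and reached 10.02 ± 2.09 CPM in DAPT (log2 fold change 4.29, SE 0.27, edgeR adjusted p = 6.26e-14). TRINITY_DN1523_c0_g1 was already abundant in DMSO, at 50.3 ± 11.5 CPM, and rose 4.67-fold to 235 ± 45.9 CPM (log2 fold change 2.22, SE 0.16, edgeR adjusted p = 2.90e-12). In each of these 4 genes all 6 DAPT libraries lay beyond all 6 DMSO libraries at 0 h.

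The calls at 0 h come from edgeR's quasi-likelihood F test, in which 1826 genes had an unadjusted p under 0.05 where chance would give 613. With surrogate variables, added after seeing the data, 1869 genes were called, of which 65.5% were lower. Scaling by library totals alone moved the median log2 fold change of all genes from 0.01 to 0.12 at 0 h and from -0.02 to 0.10 at 6 h, and gave 480 lower and 249 higher genes at 0 h, so that 65.8% of the calls were lower.

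**Figure D1:**
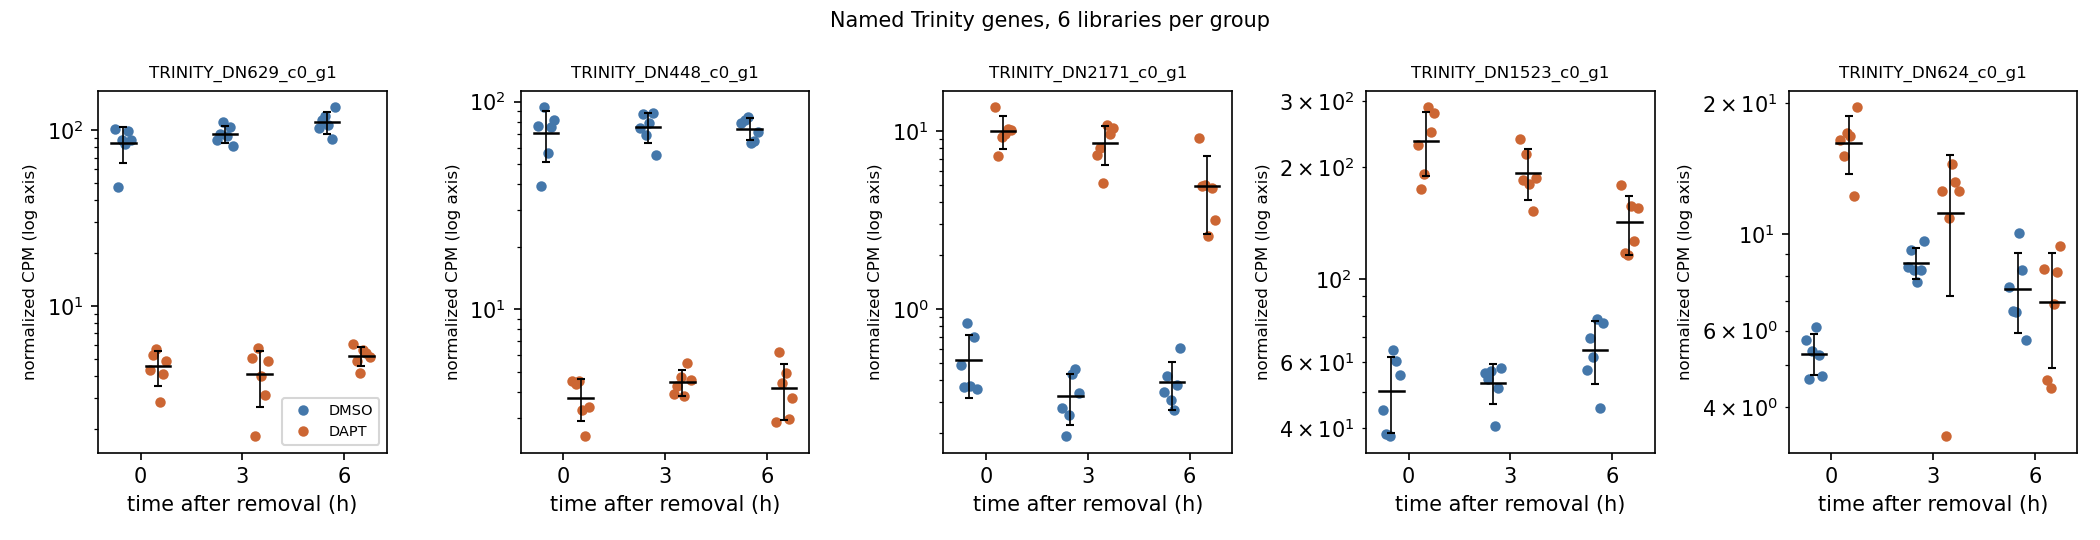
CPM (log axis) of 5 Trinity genes by time after DAPT removal in hours, with a point per library, DMSO in blue and DAPT in orange, and bars for the mean ± SD of 6 libraries. TRINITY_DN629_c0_g1 and TRINITY_DN448_c0_g1 stood at or below 6.20 CPM in the DAPT libraries, while in TRINITY_DN624_c0_g1 the groups stood apart at 0 h (5.31 against 16.2 CPM) and overlapped at 6 h.

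At 3 h after removal, the excess of lower genes was still present. There were 594 genes lower and 197 higher in DAPT than in DMSO animals of the same time, so that 75.1% of the 791 called genes were lower. The medians were -1.33 and 0.94 on the log2 scale, and 417 lower and 94 higher genes differed at least 2-fold. TRINITY_DN629_c0_g1 was 22.9-fold lower, at 4.11 ± 1.45 against 95.6 ± 10.8 CPM (SE 0.21 on the log2 scale, edgeR adjusted p = 1.66e-17), and TRINITY_DN448_c0_g1 stood at 4.46 ± 0.627 against 75.5 ± 12.2 CPM. TRINITY_DN2171_c0_g1 stood at 8.57 ± 2.16 against 0.326 ± 0.104 CPM, and TRINITY_DN1523_c0_g1 at 193 ± 30.1 against 52.7 ± 6.44 CPM (3.66-fold, edgeR adjusted p = 1.63e-10). All 6 DAPT libraries lay beyond all 6 DMSO libraries in 378 of the 594 lower and 101 of the 197 higher genes. By edgeR's test, 1856 genes had an unadjusted p under 0.05. With surrogate variables 1807 genes were called, 64.0% of them lower, and 511 of the 791 differed at least 2-fold.

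At 6 h the called genes were fewer, with 483 lower and 139 higher in DAPT, and 77.7% of the 622 were lower. The medians were -1.47 and 1.04 on the log2 scale, and 374 lower and 72 higher genes differed at least 2-fold. TRINITY_DN629_c0_g1 was still 21.3-fold lower in DAPT, at 5.21 ± 0.663 against 112 ± 16.0 CPM (edgeR adjusted p = 1.97e-17), and TRINITY_DN448_c0_g1 stood at 4.18 ± 1.28 against 73.9 ± 8.94 CPM. Of the rising genes, TRINITY_DN2171_c0_g1 stood at 4.93 ± 2.30 against 0.388 ± 0.118 CPM (11.7-fold, edgeR adjusted p = 1.70e-10), and TRINITY_DN1523_c0_g1 at 142 ± 25.6 against 64.8 ± 12.5 CPM (2.19-fold, edgeR adjusted p = 3.66e-06). The DAPT and DMSO libraries did not overlap in 238 of the 483 lower and 75 of the 139 higher genes. The count rested on the spread shared by the 36 libraries: a fit of the 12 libraries of 6 h alone called 414 genes, and 1526 were called with surrogate variables. With library totals alone, 175 genes were higher and 343 lower at 6 h, so that 66.2% of the calls were lower.

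**Figure D2:**
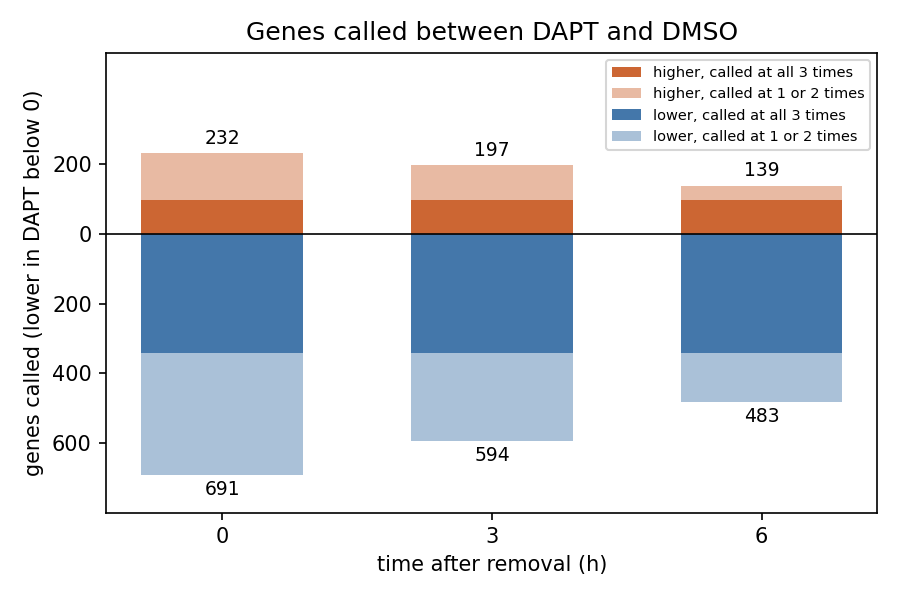
Number of genes called between DAPT and DMSO (vertical axis, genes higher in DAPT above 0 and lower below 0) by time after removal in hours. The dark part of each bar holds the genes called in the same direction at all 3 times, 98 higher and 342 lower, and the numbers at the bars give all calls.

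The question of which differences outlasted the inhibitor was followed in the genes called at 0 h. Of 1179 genes called at any time, 440 were called in the same direction at all 3 times, 342 lower and 98 higher, and 0 were called in opposite directions at different times. Of the 691 genes lower at 0 h, 477 were called lower again at 3 h and 386 at 6 h, where independent lists would share 33.5 and 27.2. Of the 232 genes higher at 0 h, 151 were called higher again at 3 h and 108 at 6 h, where independent lists would share 3.73 and 2.63. Because the comparisons share an estimate of the spread per gene, lists of calls can overlap beyond these independent values by that alone. The fitted difference kept its sign at both later times in 677 of the lower and 221 of the higher genes. The calls at 0 h alone comprised 170 lower and 71 higher genes, which does not show that their difference had ended. With surrogate variables 1000 genes were called in the same direction at all 3 times.

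The share of counts in the genes lower at 0 h stood at 14.03 ± 5.94% in DMSO and 5.77 ± 2.49% in DAPT at 3 h (exact permutation test, two-sided p = 0.00433), and at 15.8 ± 6.82% and 7.27 ± 3.50% at 6 h (exact p = 0.0195). For the genes higher at 0 h it was 1.91 ± 0.442% in DMSO and 4.83 ± 1.10% in DAPT at 3 h, and 1.59 ± 0.227% and 3.73 ± 0.440% at 6 h (exact p = 0.00216 at both times, the smallest possible).

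**Figure D3:**
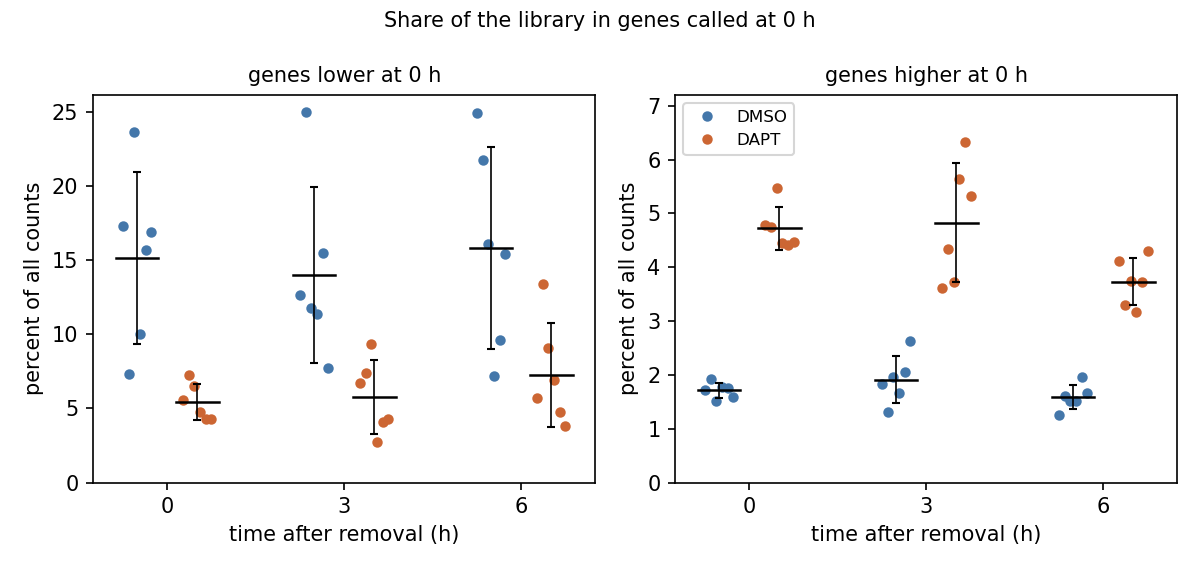
Percent of all counts in the 691 genes lower (left) and the 232 genes higher (right) in DAPT at 0 h, by time after removal in hours, with a point per library, DMSO in blue and DAPT in orange, and bars for the mean ± SD of 6 libraries. At 6 h the genes higher at 0 h took 3.18% to 4.31% of the counts in DAPT and 1.26% to 1.96% in DMSO.

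Over the genes called at 0 h, the slope of the 3 h log2 fold changes on those of 0 h was 0.843 for lower and 0.859 for higher genes, and that of the 6 h fold changes 0.803 and 0.695. Selection at 0 h inflates the 0 h fold changes and so lowers these slopes. With genes called in the other replicates, and the response taken as the mean DAPT minus the mean DMSO slope, that of the lower genes at 3 h was 1.00 times that at 0 h (exact permutation of the time labels, two-sided p = 0.991), and at 6 h 0.961 times (exact p = 0.722). For the higher genes it was 0.930 times at 3 h (exact p = 0.375) and 0.739 times at 6 h (exact p = 0.00788). The p of these comparisons over time are approximate, since slopes at 0 h and later were built differently. These responses were 0.804, 0.805 and 0.772 at 0 h, 3 h and 6 h for lower genes, and 0.913, 0.849 and 0.674 for higher genes. By gene, 68 of 83 genes called higher in odd replicates had a fitted change toward the control value from 0 h to 6 h in the even ones, and 37 of 67 called in even replicates had one in the odd ones. The slope of the higher genes in DAPT libraries was 0.937 ± 0.0668 at 0 h, 0.849 ± 0.116 at 3 h and 0.674 ± 0.0683 at 6 h, and that of the lower genes 0.840 ± 0.0741, 0.805 ± 0.0725 and 0.772 ± 0.121. At 0 h these DAPT slopes alone still hold some selection, since the DMSO mean subtracted includes replicates that called the genes. Subtracting the mean DMSO slope, as in the responses above, removes this. The test of the difference between both sets at 6 h gave an exact p of 0.0571, with a difference of relative responses, higher minus lower genes, of -0.222. Without DMSO 6 h replicate 4, left out after seeing the data, this difference was -0.256 with an exact p of 0.0376. At each time and in both sets the DAPT libraries lay apart from the DMSO libraries (exact p = 0.00216).

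**Figure D4:**
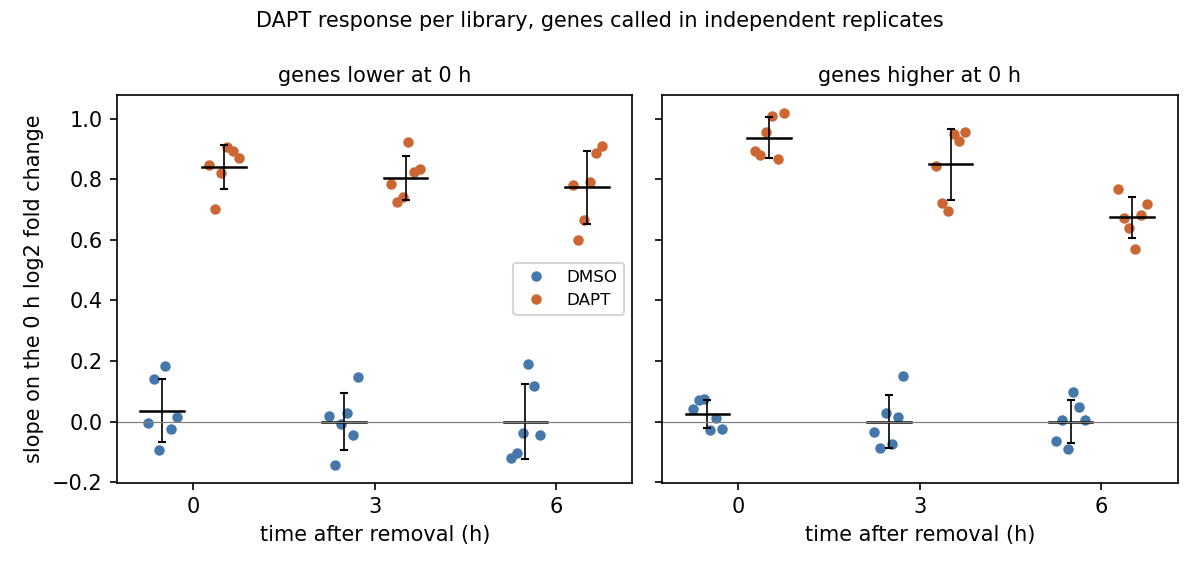
Slope of each library's log2 CPM differences from the DMSO mean of its time on the 0 h log2 fold changes, for genes lower (left) and higher (right) at 0 h in replicates other than those scored at 0 h, by time after removal in hours. Points are libraries, DMSO in blue and DAPT in orange, with mean ± SD of 6. For the higher genes, the mean DAPT minus the mean DMSO slope went from 0.913 at 0 h to 0.674 at 6 h.

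Tested gene by gene, the difference between DAPT and DMSO changed from 0 h to 6 h in 1 gene. TRINITY_DN624_c0_g1 rose with DAPT at 0 h, from 5.31 ± 0.575 to 16.2 ± 2.45 CPM (3.05-fold, edgeR adjusted p = 4.20e-07). It stood at 8.59 ± 0.688 in DMSO and 11.2 ± 3.98 CPM in DAPT at 3 h (log2 fold change 0.39, SE 0.21, edgeR adjusted p = 0.383) and at 7.48 ± 1.55 and 6.97 ± 2.06 CPM at 6 h (edgeR adjusted p = 0.978). The change from 0 h to 6 h was -1.69 on the log2 scale (SE 0.29, edgeR adjusted p = 0.0225). The DMSO values at 3 h and 6 h were above those at 0 h by 0.69 and 0.47 on the log2 scale and did not pass (edgeR adjusted p = 0.533 and 0.421). TRINITY_DN1523_c0_g1 changed by -1.09 (SE 0.22) and did not pass (edgeR adjusted p = 0.0991). In the edgeR fit with surrogate variables, added after seeing the data, its change was -0.79 and was called (adjusted p = 0.000843). The call of TRINITY_DN624_c0_g1 was lost without DMSO 6 h replicate 4 (adjusted p = 0.0613), by limma-voom (0.0770), with library totals (0.146) and on leaving out replicate number 1, 3, 4, 5 or 6 (0.131 to 0.329), while its log2 change stayed between -1.59 and -1.78 in these settings.

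From 0 h to 3 h the change of the difference passed in 0 genes by edgeR's test, with 150 genes at an unadjusted p under 0.05 where chance would give 613. DESeq2 and limma-voom called 0 genes as well, and the fit with surrogate variables 7. From 0 h to 6 h, 477 genes had an unadjusted p under 0.05 in edgeR's test, DESeq2 called 4 genes, limma-voom 0 and the fit with surrogate variables 8. In simulated counts, 20% of genes with a 2-fold change of the difference from 0 h to 6 h were recovered. At this depth and replication, most such changes would have been missed. The simulation held more changed genes than were called here, which makes the BH threshold easier to pass, so real recovery may be lower. The change to 3 h was not simulated.

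In control animals, 0 genes were called between 3 h and 0 h and 0 between 6 h and 0 h by edgeR's test. The counts at an unadjusted p under 0.05 were 1134 and 1376, where chance would give 613, and the smallest adjusted p were 0.272 and 0.140. The excess over chance rested on single libraries or replicate numbers: without DMSO 6 h replicate 4 the count at 6 h was 584, and leaving out a replicate number gave 315 (without 6), 526 (without 4) and up to 2275 (without 1) at 3 h and 595 (without 4) to 2544 (without 1) at 6 h. DESeq2 called 2 and 10 genes, limma-voom 0 and 0, and the fit with surrogate variables 53 and 7. The 4 genes named for 0 h moved by -0.62 to 0.40 on the log2 scale between control times, and none of them was called (edgeR adjusted p from 0.416 to 0.887).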

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

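The 3 tests on the smaller effect at 6 h in genes higher at 0 h were written after that result was seen. In each of the 6 groups, several measures were examined for a library far from the others, 72 checks in all. Of these checks, 6 found one, where chance gives about 3.6. The measures overlap, so the checks are not independent of each other.

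The effect of DAPT on genes higher at 0 h was 0.739 times as large at 6 h as at 0 h, while that on genes lower at 0 h was 0.961 times as large. Selection of the genes at 0 h as the whole cause is argued against, since the 0.739 was measured with genes called and weighted in other replicates (exact p = 0.00788), but the drop was uneven: of genes called in odd replicates 81.9% had a fitted change toward control in the even ones (median log2 change -0.50), and of those called in even replicates 55.2% in the odd ones (37 of 67, median -0.14), and of the genes lower at 0 h the same shares were 65.5% (median 0.20) and 58.5% (median 0.12). The DMSO 6 h library that stood apart is argued against by 0.765 without it (exact p = 0.0130), and leaving out each replicate number in turn gave 0.687 to 0.778. Without number 4 or 6, however, only 8 or 6 genes were called higher in the even replicates, against 67 with all libraries. Whether the genes lower at 0 h share the drop cannot be told apart, because their shares with a fitted change toward control overlap with those of the higher genes. The difference between both sets was -0.222 with an exact p of 0.0571, and -0.256 with 0.0376 without that DMSO library. A return of the genes that had risen toward control levels within 6 h of removal may be a candidate explanation, which the design names and which stays a hypothesis, because it was found and tested on the same data.

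TRINITY_DN624_c0_g1 was flagged because its difference between DAPT and DMSO changed between times, by -1.69 on the log2 scale from 0 h to 6 h (edgeR adjusted p = 0.0225). A library stood far from the other 5 of its group in these measures. The 20 most abundant genes took 39.03% of the counts in DMSO 3 h replicate 2, against 24.84% to 28.97%, and 32.21% in DAPT 3 h replicate 2, against 25.7% to 27.15%. Genes higher at 0 h took 5.471% of the counts in DAPT 0 h replicate 3, against 4.408% to 4.785%. TRINITY_DN629_c0_g1 stood at 47.65 CPM in DMSO 0 h replicate 2, against 83.81 to 101.5 CPM. TRINITY_DN2171_c0_g1 stood at 9.152 CPM in DAPT 6 h replicate 1, against 2.582 to 4.994 CPM. TRINITY_DN624_c0_g1 stood at 3.43 CPM in DAPT 3 h replicate 2, against 10.9 to 14.52 CPM, and without replicate number 2 its difference at 3 h was called (log2 fold change 0.59, edgeR adjusted p = 0.0279).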

How the results depend on the processing

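The fits with surrogate variables and without DMSO 6 h replicate 4 were chosen after seeing the data, and so was the form of the slopes on independent replicates (per library), though not their use. Of the counts and slopes, 150 alternatives stayed within 1.5 times the count or 1 SD of the slope and 26 did not; of the tests of named genes, 260 kept their side of the threshold, 8 lost the call and 2 gained it. No called value changed sign, while the uncalled value of TRINITY_DN624_c0_g1 at 6 h (-0.07 on the log2 scale) was between 0.01 and 0.07 in 5 settings. No gene called between DAPT and DMSO was called in the opposite direction under any alternative run for these comparisons. The causes of the shifts below were not tested, except where fewer libraries or a stricter threshold make them.

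With 5 surrogate variables 1869, 1807 and 1526 genes were called at 0 h, 3 h and 6 h, 1000 at all 3 times, 7 and 8 for the change to 3 h and 6 h, and 53 and 7 for DMSO at 3 h and 6 h. The slopes of the lower genes were then 0.924 at 3 h and 0.985 at 6 h. On independent replicates, without surrogate variables, the values were 1.00 and 0.961. At 3 h, 491 genes passed an adjusted p of 0.01 and 511 differed at least 2-fold. At 6 h, a fit of those 12 libraries called 414. For the change to 6 h, DESeq2 called 4 genes, limma-voom 0 and the fit without DMSO 6 h replicate 4 called 0. With library totals, and without replicate number 1, the 1 gene called was not TRINITY_DN624_c0_g1. With library totals it changed upward (1 higher, 0 lower). Both settings are among the 150 alternatives that stayed, since only the number of genes was compared. For DMSO at 3 h and 6 h DESeq2 called 2 and 10. Leaving out each replicate number in turn gave 713 to 802 genes at 0 h, 569 to 636 at 3 h, 447 to 581 at 6 h, 0 to 2 for the change to 6 h and 307 to 368 at all 3 times.

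Whether libraries of the same replicate number belong together is not known. Within a time, 11 of 18 same-numbered pairs correlated over 0.1 (range -0.583 to 0.502), and 5 of 18 DAPT libraries correlated best with their own number. No reference for unpaired libraries was computed, so these values do not decide it. With a replicate block over all groups 927, 770 and 613 genes were called at 0 h, 3 h and 6 h, 443 at all 3 times, 0 and 1 for the changes, and 0 and 0 for DMSO over time, with slopes of 0.848 and 0.804 for lower and 0.876 and 0.681 for higher genes at 3 h and 6 h. A replicate block within the 12 libraries of a time gave 866, 671 and 293. Without DMSO 6 h replicate 4, 977, 846 and 626 genes were called. Depth and replication limit changes under 2-fold and changes of the difference, and a gene at 0 in any library is outside the table.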

Other observations

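The DAPT animals themselves were compared over time only after the data had been seen, and the fit with surrogate variables was also added then, whereas the tests on the first axis and on co-variation were written before their results. Between 0 h and 3 h after removal 0 genes were called in DAPT animals by edgeR's test, with 1061 at an unadjusted p under 0.05. Between 0 h and 6 h, 66 were called, 40 higher and 26 lower at 6 h. Of the 40 that rose, 6 had been lower in DAPT than in DMSO at 0 h, and of the 26 that fell, 10 had been higher. Among all 12253 genes tested, 691 were lower and 232 higher at 0 h. Both comparisons use the same DAPT libraries of 0 h, so part of this overlap is built in. Of the 66, 54 had a fitted change of the same sign in DMSO animals, with a median of 0.29 on the log2 scale in that direction against 0.93 in DAPT. The count rests on single libraries. It was 14, 51, 57, 8, 3 and 36 without DAPT 0 h replicate 1, 2, 3, 4, 5 or 6. Without DAPT 6 h replicate 1, 2, 3, 4, 5 or 6 it was 481, 44, 8, 40, 21 and 2.

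Some genes were called late and at neither earlier comparison. At 6 h these were 68 lower and 25 higher genes, and 88 lower and 40 higher genes were called at 3 h alone. None of them passed the edgeR test of a change of the difference between times.

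The genes lower at 0 h varied together between DMSO libraries of the same group. Their mean pairwise correlation across the 18 DMSO libraries, with group means removed, was 0.125, against a median of 0.00437 and a highest value of 0.0154 in 1000 random sets of uncalled genes matched on abundance. The genes higher at 0 h did so too (0.0436, against a highest value of 0.0213 in their matched sets), and genes are not independent replicates, and 6 of these libraries were those of the 0 h comparison. The axis of variation that all genes share is argued against, since with it removed the correlation was 0.134, and without DMSO 6 h replicate 4 it was 0.115. A shared source of the transcripts of the lower genes, such as cells whose number differs between samples of about 25 animals, may explain it (0.125), and which cells these would be was not tested.

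Variation within groups had a dominant first axis, which held 38.5% of the variance over 36 libraries, against 13.6% for the second. DMSO 6 h replicate 4 lay at one end (-91.05), beyond the next library (-63.13). Sequencing depth is argued against, with Spearman's rho = 0.179 (95% bootstrap interval -0.106 to 0.437, permutation p = 0.316, BH adjusted 0.632) and Pearson's r = 0.195 (permutation p = 0.318, adjusted 0.636; 0.133 without the 2 libraries of most extreme depth). The share of the 20 most abundant genes is argued against too, with rho = -0.035 (interval -0.364 to 0.281, p = 0.844, adjusted 0.844) and r = 0.0141 (p = 0.934, adjusted 0.934; -0.0685 without 2 libraries). The TMM factor was not tested against the axis. At 0 h and at 6 h, in DMSO and in DAPT, the lowest library on the axis also had the lowest TMM factor of its group. This was so in neither group of 3 h. Other technical causes thus remain open. The lane of each library is not given in the sources used here, and no biological explanation was tested, since the design gives none within a group.

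Other splits of the same libraries into groups of the same sizes were counted, 100 per comparison with the real split included. At 0 h, 2 of 100 splits, the real one included, gave at least as many calls as the real 923 (highest other 1490). At 3 h it was 1 of 100, the real split itself (real 791, highest other 1). Such counts were rare among the splits, but at 0 h the count alone does not exclude chance, since another split gave more calls. At 3 h, in libraries that share none with 0 h, 477 of the 691 lower and 151 of the 232 higher genes were called again. In the opposite direction 0 were called, which argues against chance for the genes called again. At 6 h it was 5 of 100 (real 622, highest other 1700), so chance cannot be excluded by this count. The 4 other splits of 6 h, with 720 to 1700 calls, correlated at 0.634 to 0.725 with the first axis of the 6 h libraries and the real split at 0.0247. Splits with 1 to 78 calls correlated at 0.231 to 0.502. Splits without calls were not examined for this, so how often such a correlation comes without calls is not known. The genes of the real split had the same sign at 0 h in 98.6% and at 3 h in 99.4%. The libraries of 0 h and 3 h share none with 6 h. For the 4 other splits, whose direction is arbitrary, the larger of the same-sign and opposite-sign shares was taken. It was 65% to 91.7% at 0 h and 59.5% to 80.5% at 3 h, and taking the larger share can only raise these values. For the change to 3 h, 100 of 100 splits gave as many as the real 0 (highest other 545), and for the change to 6 h 1 of 100 (real 1, highest other 0). The latter rests on a single gene, whose call several settings lose while its log2 change stays between -1.59 and -1.78, and a count of 1 against 0 is weak evidence on chance. For DMSO at 3 h and at 6 h, 100 of 100 splits gave as many as the real 0 (highest others 0 and 6). Here and for the change to 3 h, a real count of 0 makes 100 of 100 certain, so these counts test nothing. With surrogate variables, 40 orders of the time labels were counted, the real one included. Of these, 2 of 40, again with the real one, gave at least the real 8 genes with a changed difference at 6 h (highest other 61). Chance cannot be excluded for these genes.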
